A study of Tetrahymena thermophila with 4 samples.

How the data were processed

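Total RNA was isolated from mating Tetrahymena thermophila cells with a small RNA kit, per the labels' protocols. For the oxidation-resistant library the RNA was treated with sodium periodate before cloning, and for the others it was not. The protocols describe gel selection between size markers of 26 and 32 nt with a few bases on either side, then ligation of a 3′ and a 5′ adapter, reverse transcription and PCR. Gel selection, adapter ligation and PCR can each favour some RNA ends, and lengths at the edges of the excised gel region may be recovered less evenly. The labels place the libraries in 4 groups by genotype, RNA treatment and time after mixing, with 1 library per group.

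The files used were 21 tables of base composition, 1 list of free-energy differences and 1 table of mismatches. Per the file headers and the values, the composition tables hold the percent of RNAs with A, C, G or U at each position, computed by the authors for a single RNA length. The rows sum to 100 or slightly less. The share with none of the 4 listed bases was 0.284% to 1.20% at position 1 and at most 0.193% elsewhere, leaving aside the set without 5′ U. The free-energy list is headed ddG and gives no unit, sign convention or RNA identity, and the mismatch table gives no unit or denominator. Read trimming, aligner, genome build, filters, whether identical reads were collapsed, and how the set without 5′ U was selected are not given in the sources used here. No file holds read counts, so the depth of each library is unknown, no interval or detection limit was computed for any share, and shares of rare lengths may be less precise than those of common ones.

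Shares were used as deposited. Positions were counted from the 5′ end, and the last 3 positions of each length also from the 3′ end. The interior of an RNA ran from position 5 to the position 5 before its last, which is position 24 of a 29 nt RNA. Differences between libraries were taken in percentage points. As a yardstick, each was divided by the SD over interior positions of the same base's difference, and 2 such SDs were taken as the limit for calling a difference. The mean difference over the interior was not subtracted, so a shift of a base along the whole RNA can pass this limit by itself. Interior U, for example, was 2.57 points higher in oxidation-resistant than in whole RNA of wild type cells at 3 h, with an SD of 1.02. This yardstick was chosen after the composition tables had been seen, and it does not measure variation between cultures or libraries. No test across libraries was made because no group had more than 1 library.

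The positions named in the text followed a rule fixed before the data were examined. Positions 1, 2, the last, the second from the last and the third from the last were named in every comparison, together with the 3 pairs of position and base with the greatest absolute difference elsewhere in each 29 nt comparison. For the mismatch table the 3 highest and 3 lowest values were named. The comparisons and the alternatives were also fixed before the data were examined, except those given as added later. Rescaling the shares to the 4 listed bases was run as the alternative and the deposited shares as the main values, while the plan named them the other way round.

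For ddG the mean, SD, median, quartiles and share below 0 were computed, with an exact Clopper-Pearson 95% interval and an exact binomial test after leaving out values within 0.05 of 0; the binomial test was added after the data were seen. Mismatch values were divided by the median of the interior positions of the same length. To look for duplex ends, each base share was compared with that of the complementary base at the position it would face in a duplex with a 3′ overhang of 0 to 4 nt. To look for an abundant sequence in the set without 5′ U, the raised base was taken at each of positions 6 to 21 and its excess over the same base elsewhere was averaged. On simulated RNAs, 20000 for each overhang, the first procedure recovered 5 of 5 overhangs, with or without the first facing pair. The pair left out of the simulations was that of the simulated overhang. In the data the positions left out were always position 1 and the third from the 3′ end. The reduced simulations therefore match the procedure used on the data only for the 2 nt overhang. The second procedure recovered 16 of 16 bases of a sequence added at 8% and estimated its share as 7.99%, while a set with no added sequence gave 0.525%. For the second procedure the simulated background had the same composition at every position, so it varied less along the RNA than the data did. Calculations used Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9.

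Alternatives were the excess over the interior mean or over the mean of all positions, rescaled shares, lengths 27 to 30 nt alone, positions counted from the 5′ end, the median and a mean without the lowest and highest 5% of ddG values, and mismatch values without the first and last position. No genome sequence was used here, so no RNA was placed on a chromosome or gene.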

Results

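Small RNAs were sequenced from mating cells of Tetrahymena thermophila, a ciliate that keeps a germline micronucleus and a somatic macronucleus in the same cell. During conjugation a Dicer enzyme produces small interfering RNAs that are bound by Twi1p, the Piwi-family Argonaute protein encoded by TWI1. There were 4 libraries, 1 in each group. At 3 h after mixing, the groups were whole RNA of wild type cells (strains B2086 and CU428 mated with each other), oxidation-resistant RNA of the same wild type cross, and whole RNA of cells without TWI1 in either nucleus. The other group was whole RNA of wild type cells at 6 h after mixing. Periodate oxidises the free 2′,3′ hydroxyl pair at an RNA's 3′ end and so blocks adapter ligation, whereas a 3′ end with a 2′-O-methyl group is left ligatable. The libraries without oxidation hold RNAs with either kind of end.

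The values were the percent of RNAs of a given length that had A, C, G or U at each position, counted from 1 at the 5′ end. The 29 nt class was used from all 4 libraries, and lengths 24 to 32 nt were used from the wild type oxidation-resistant and TWI1 knockout libraries. The files gave no read counts, so the depth is unknown and no counting interval could be given. Because there were no replicates, no difference between libraries could be set against replicate error and no test across libraries was made. Each 29 nt difference was instead set against the standard deviation of the same base's difference over positions 5 to 24, called the interior SD here, which describes variation along the RNA and not between cultures. The values hold no measure of TWI1 RNA, so the knockout label was not checked against the targeted gene.

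The first comparison asked how RNAs with a protected 3′ end differed from all RNAs of wild type cells at 3 h. Protected 29 nt RNAs began with U far more often, at 92.6% against 72.3% of whole RNA, a difference of 20.4 percentage points (interior SD 1.02). A at position 1 was correspondingly less common, at 3.66% against 18.9%. At position 27, the third from the 3′ end, A was the commonest base in both libraries but was lower among protected RNAs, at 54.7% against 63.4% (interior SD 0.724). The protected RNAs ended in U more often, at 61.9% against 51.0%. At position 27, U was 28.9% among protected RNAs and 21.6% in whole RNA. G at position 28 was 12.3% against 18.4%, and U there was 44.7% against 40.3%. At position 29, C was 10.9% against 15.4% and G was 4.76% against 8.70%. At position 2, A was 39.7% and 40.5%, a difference below 2 interior SDs, and U was 31.4% and 27.9%. Outside these 5 end positions, the differences of greatest size were U at position 26 (42.59% against 37.02%), U at position 25 (42.6% against 37.4%) and C at position 25 (19.4% against 24.4%). Protected RNAs were also richer in U along the interior, by 2.57 points on average, and poorer in G, with a mean difference of -1.40 points. Differences in U therefore depended on the baseline. As an excess over the mean of all positions, ends included, they were 7.19 points at position 29, 3.46 at position 27, 1.79 at position 26, 1.48 at position 25, 0.666 at position 28 and -0.180 at position 2. The last 4 of these were below 2 interior SDs, and on the same baseline G differed by -1.35 points at position 1 and -2.44 points at position 29. Over the interior mean, U differed by 2.99 points at position 26 and 2.68 at position 25, both above 2 interior SDs. On that baseline it differed by 1.87 points at position 28 and 1.03 at position 2, both below 2 interior SDs.

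**Figure D1:**
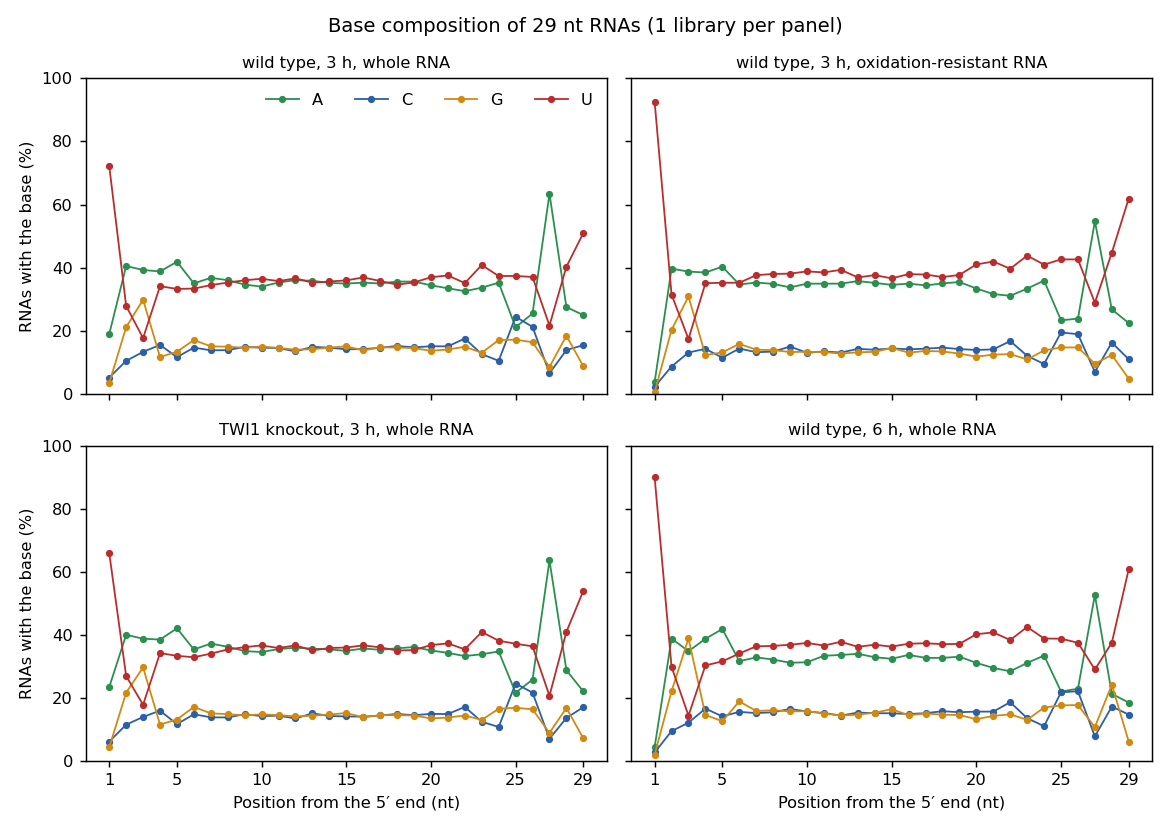
Percent of 29 nt RNAs with A, C, G or U (vertical axis) at each position from the 5′ end (horizontal axis, nt), with 1 library per panel and lines joining the positions. U at position 1 was 72.3% in wild type whole RNA at 3 h, 92.6% in oxidation-resistant RNA, 65.9% in the TWI1 knockout and 89.9% at 6 h, and every panel has a peak of A at position 27.

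The second comparison asked how 29 nt RNAs differed when cells lacked Twi1p, with time and RNA treatment alike. The knockout and wild type whole RNA profiles lay close together, with a mean absolute difference of 0.464 points over all positions and bases, against 2.06 points between oxidation-resistant and whole RNA of wild type cells. U at position 1 was less common in the knockout, at 65.9% against 72.3%, a difference of -6.34 points (interior SD 0.295). A took most of the remainder, at 23.4% against 18.9%. A at position 27 was nearly equal, at 63.6% in the knockout and 63.4% in wild type, a difference of 0.145 points that was below 1 interior SD. C at position 1 was 6.08% against 5.13%, and G was 4.24% against 3.31%. The 3′ terminal base was U in 53.9% of knockout and 51.0% of wild type RNAs, A in 21.98% and 24.95%, and C in 17.01% and 15.40%. G at position 28 was 16.8% in the knockout and 18.4% in wild type. At position 2, C was 11.5% against 10.4%, U was 26.9% against 27.9% and G was 21.6% against 21.1%, each above 2 interior SDs, while A, at 39.95% against 40.51%, was not. As an excess over the interior mean or over the mean of all positions, however, this A differed by -0.79 and -0.80 points, both above 2 interior SDs (SD 0.325). Outside the end positions the differences of greatest size were A at position 21 (0.790 points), U at position 24 (0.766 points) and U at position 26 (-0.716 points). Over the mean of all positions, those of A at position 21 (0.554 points) and U at position 26 (-0.526 points) were below 2 interior SDs. Over the interior mean, A at position 21 (0.56 points) was again below 2 interior SDs but U at position 26 (-0.717 points) was above.

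The third comparison set wild type whole RNA at 6 h against that at 3 h. At 6 h, 29 nt RNAs began with U in 89.9% of cases against 72.3% at 3 h, a difference of 17.7 points (interior SD 1.15), and with A in 4.31% against 18.9%. A at position 27 was lower, at 52.6% against 63.4% (interior SD 0.995), and U there was 28.95% against 21.64%. The share ending in U was 60.8% against 51.0%. G at position 28 was higher at 6 h, at 24.1% against 18.4%, whereas oxidation-resistant RNA at 3 h had 12.3%. A at position 28 was 21.2% at 6 h and 27.5% at 3 h, and U there was lower at 6 h, at 37.4% against 40.3% (-4.75 points as an excess over the mean of all positions). Among the other positions, G at position 3 differed most, at 38.8% against 29.8%, followed by A at position 3 (34.8% against 39.2%) and A at position 22 (28.4% against 32.5%). At position 2, the shares as deposited differed by less than 2 interior SDs for all 4 bases, with A at 38.8% and 40.5%. As an excess over the interior mean, however, C at position 2 differed by -1.94 points, which was above 2 interior SDs (SD 0.507), and the difference in A turned from -1.75 to 0.952 points. Interior A was lower at 6 h, with a mean difference of -2.70 points, and interior U was higher by 1.34 points. As an excess over the interior mean, A differed by -1.78 points at position 3 and -1.43 points at position 22, both below 2 interior SDs, and by -3.54 points at position 28.

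The fourth comparison followed the end composition through RNA lengths 24 to 32 nt in the oxidation-resistant wild type library and the TWI1 knockout library. A U at position 1 was more common in oxidation-resistant RNA at 9 of 9 lengths, with a median difference of 26.7 points and a range of 9.89 to 28.2 points. In oxidation-resistant RNA it was 73.9% at 24 nt, 93.4% at 30 nt and 90.6% at 32 nt, whereas in the knockout it lay between 55.5% at 26 nt and 66.5% at 32 nt. A at the third position from the 3′ end exceeded A at every other position from position 4 onward at 9 of 9 lengths in each library, so the peak moved with the 3′ end. This A was 43.3% at 24 nt and 64.9% at 30 nt in the knockout, and 50.4% and 55.0% in oxidation-resistant RNA. It was lower in oxidation-resistant RNA at 6 lengths (27 to 32 nt) and higher at 3 lengths (24 to 26 nt), with a median difference of -7.24 points. A 3′ terminal U was more common in oxidation-resistant RNA at 7 lengths and less common at 24 and 25 nt, with a median difference of 6.53 points. It reached 71.4% at 32 nt in oxidation-resistant RNA, against 59.7% in the knockout. U at the second position from the 3′ end was higher in oxidation-resistant RNA at 9 of 9 lengths, by a median of 3.81 points, and A there was lower at 9 of 9, with a median difference of -2.46 points. As an excess over the interior mean this U was higher at 8 of 9 lengths, the exception being 32 nt, by a median of 1.24 points, and the median for A was -1.51 points. At position 28 counted from the 5′ end, U differed by a median of 6.44 points over the lengths that reach it. A at position 2 lay between 37.7% and 40.7% over both libraries and all lengths, and G there differed by up to 5.60 points, at 24 nt. As an excess over the interior mean the 3′ terminal U differed by a median of 3.97 points, and A at position 27 counted from the 5′ end differed by a median of -1.21 points over the lengths that reach it. Genotype and oxidation differ together between these libraries, and only at 29 nt does wild type whole RNA at 3 h separate them. There the 26.7 points for U at position 1 were made up of 20.4 points between oxidation-resistant and whole RNA of wild type cells and the difference of -6.34 points between knockout and wild type whole RNA, while for A at position 27 these were -8.73 and 0.145 points. The lengths are size classes of the same libraries and not replicates.

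**Figure D2:**
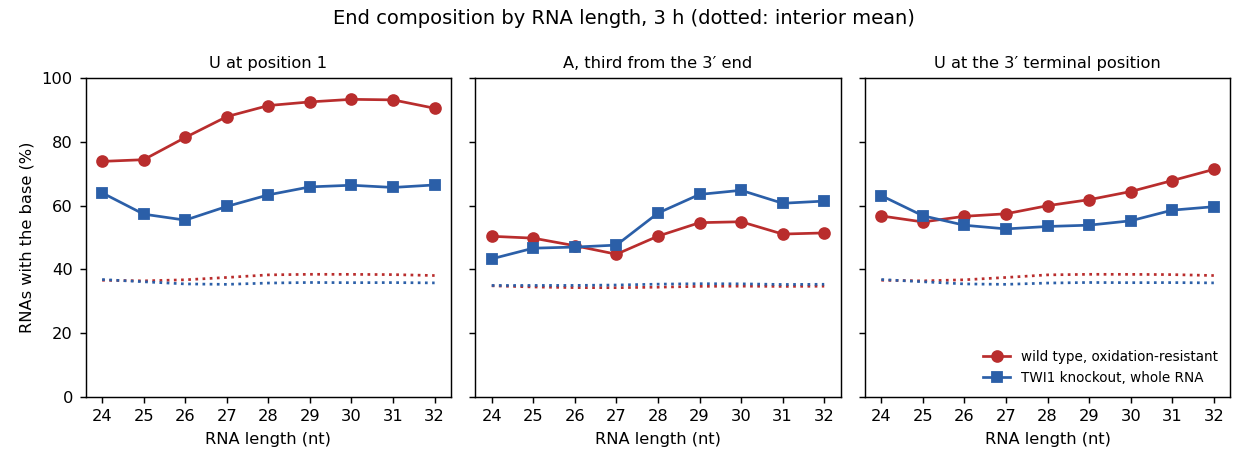
Percent of RNAs (vertical axis) with U at position 1, A at the third position from the 3′ end, or U at the 3′ end, by RNA length in nt (horizontal axis), for oxidation-resistant wild type RNA (circles) and TWI1 knockout whole RNA (squares) at 3 h, 1 library each, with dotted lines for the mean share of the base over interior positions. U at position 1 is higher in oxidation-resistant RNA at 9 of 9 lengths, while the A curves cross between 26 and 27 nt.

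The fifth comparison asked what the rest of the molecule looked like in 29 nt knockout RNAs that did not begin with U. These RNAs began with A in 65.8%, C in 16.3% and G in 17.8% of cases. A at position 27 was 69.8%, against 63.6% among all 29 nt knockout RNAs, a difference of 6.27 points (interior SD 2.99). The 3′ terminal base was C more often, at 24.32% against 17.01%, and G at position 28 was 26.1% against 16.8%. U at position 2 was 16.8% against 26.9%. U at position 29 was 49.1% against 53.9%, a difference below 2 interior SDs that was -1.74 points as an excess over the interior mean. The differences of greatest size elsewhere were G at position 26 (24.6% against 16.3%), G at position 15 (22.9% against 15.1%) and G at position 10 (22.5% against 14.7%). Taken over the interior mean, the differences in G were 5.06, 4.57 and 4.57 points at positions 26, 15 and 10 and 6.16 points at position 28, all below 2 interior SDs. The interior SD of the difference was 3.22 for G here, against 0.194 between knockout and wild type whole RNA. Positions 10 and 15 lie within that interior, so the raised G there widens the SD it is set against. Falling below 2 such SDs therefore does not show these differences in G to be background. RNAs with A, C or G at position 1 made up 33.7% of the profile of all 29 nt knockout RNAs, and among those the first base was A in 69.4%, C in 18.1% and G in 12.6%. The set without 5′ U thus held 5.24 points more G at position 1 than the profile of all RNAs implies, and the 2 profiles do not describe exactly the same RNAs. An abundant sequence, estimated below as 6.64% of the set, may add to the differences listed here. They therefore need not hold for most RNAs without 5′ U.

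**Figure D3:**
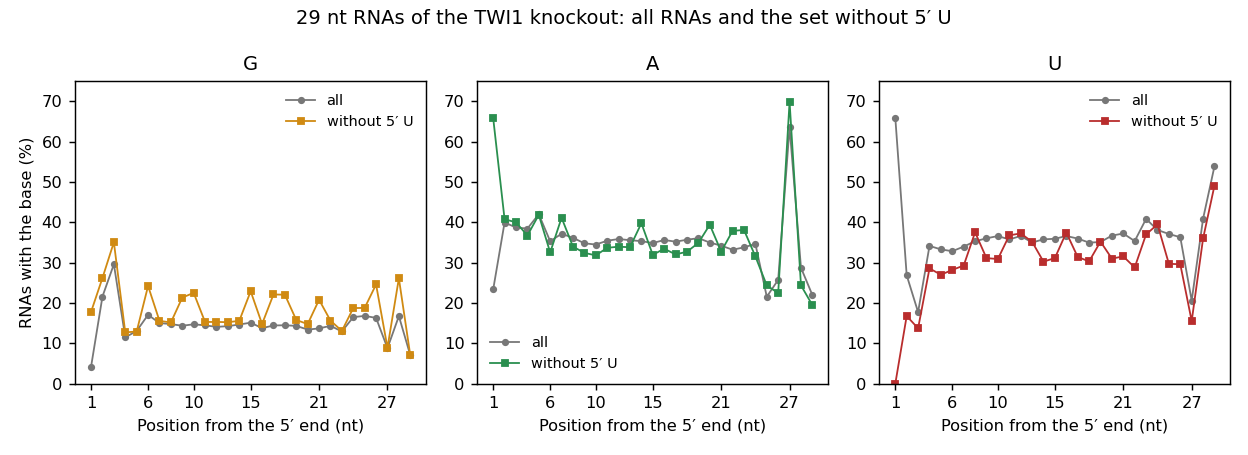
Percent of 29 nt TWI1 knockout RNAs (vertical axis) with G, A or U at each position from the 5′ end (horizontal axis, nt), for all RNAs (grey circles) and for the set without 5′ U (coloured squares), from 1 library. The set without 5′ U has steps at interior positions, such as 22.5% G at position 10 against 14.7% among all RNAs.

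For the oxidation-resistant wild type RNAs a list of 2129 free-energy differences, headed ddG, was given. Neither the unit, the sign convention nor the RNA behind each value is stated, so a sign cannot be read as a more or less stable 5′ end. The values were nearly balanced about 0, with a mean of -0.0494 (SD 2.01, SE 0.0436), a median of 0 and quartiles of -1.5 and 1.3. Their distribution was not symmetric in shape. For example, -0.7 and -0.9 held 71 and 67 entries against 28 and 26 at 0.7 and 0.9, while 0.2 held 94 against 69 at -0.2. They ranged from -6 to 6.9, with 41.8% within 1 of 0 and 12.4% more than 3 from 0. Values below 0 numbered 1051, or 49.4% (exact Clopper-Pearson 95% interval 47.2% to 51.5%), against 972 above 0 and 106 at 0. Without the values at 0, 52.0% of 2023 lay below 0 (interval 49.7% to 54.2%), and an exact two-sided binomial test against equal shares gave p = 0.0829. The intervals and the test hold only if the values come from independent RNAs, and they cover counting error within this library only.

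**Figure D4:**
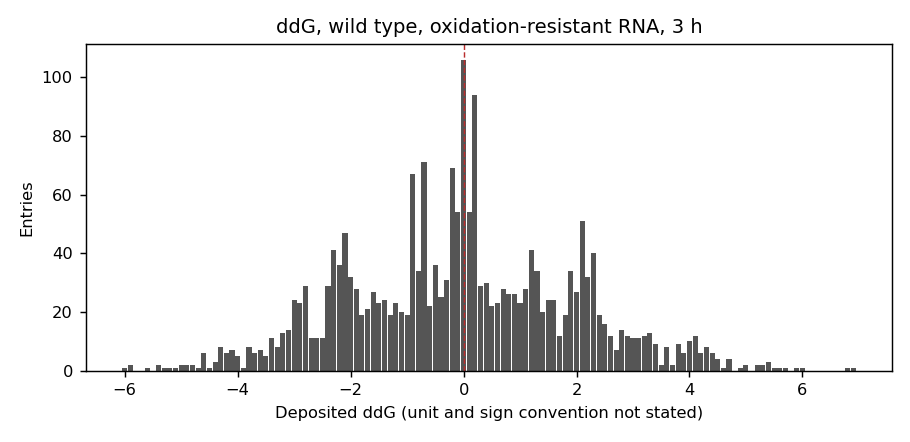
Number of entries (vertical axis) at each deposited ddG value (horizontal axis, unit and sign convention not stated) for oxidation-resistant wild type RNA at 3 h, with a dashed line at 0. Of 2129 entries, 1051 lie below 0 and 972 above.

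For the TWI1 knockout RNAs a table gave a mismatch value for each position at lengths 24 to 32 nt. Its unit and denominator are not stated, so positions are compared as ratios within a length. The value at the 3′ terminal position exceeded the median of interior positions at all 9 lengths, by a median ratio of 1.77. The ratio was 2.14 at 24 nt, 1.45 at 27 nt, 1.68 at 29 nt and 3.46 at 32 nt. The terminal position had the highest value at 7 lengths, and position 2 had it at 27 and 28 nt. The 5′ end was also above the interior median, with ratios of 1.29 to 1.51 at position 1 and 1.39 to 2.13 at position 2. Single interior positions were higher in the longest RNAs. At 32 nt, position 5 (6.81) exceeded positions 1 (4.18) and 2 (6.09). At 31 nt, positions 5 (5.69) and 13 (5.43) exceeded position 1 (4.23). The highest deposited values, listed as they stand and not as a comparison between lengths, were 11.95 at position 24 of 24 nt RNAs, 9.92 at position 32 of 32 nt RNAs and 9.70 at position 31 of 31 nt RNAs. The lowest were 1.79 and 2.15 at positions 15 and 12 of 32 nt RNAs and 2.14 at position 14 of 31 nt RNAs. No wild type mismatch values were used here, so the end pattern has no control to be set against.

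**Figure D5:**
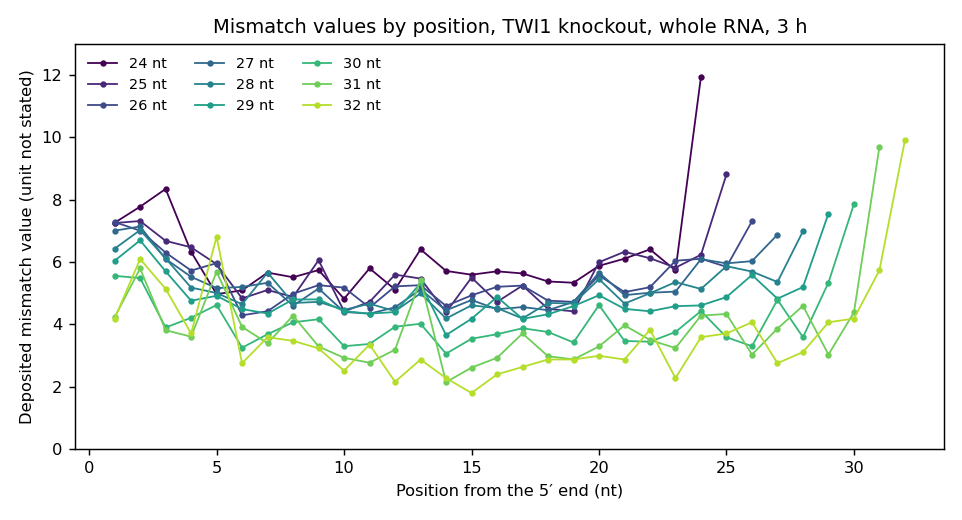
Deposited mismatch value (vertical axis, unit not stated) at each position from the 5′ end (horizontal axis, nt) for TWI1 knockout whole RNA at 3 h, with 1 line per RNA length from 24 to 32 nt. Each line turns up at its last position, where the value is 1.45 to 3.46 times the interior median.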

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

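Rescaled shares in the comparison across lengths and in the set without 5′ U, and the mismatch ratio at 29 nt alone or over the interior mean, were chosen after seeing the data; the other alternatives were planned. Values with no replicates were called moved when they changed by more than the interior SD (the SD over lengths for results across lengths, the counting interval for the ddG share). The limit across lengths was wide. For A at the third position from the 3′ end it was 6.44 points, so a change from -7.24 to -1.21 points stayed within it. Staying within the limit therefore says little about the results across lengths. Of 49 alternatives to 18 main results, 37 stayed within that limit, 12 moved, and 46 kept their sign; the sign exceptions were the median ddG of 0 and A at position 27 between knockout and wild type, which was -0.0836 and -0.0907 points as an excess over the interior and over all positions. Taken as an excess over the interior mean, the oxidation-resistant minus whole RNA difference was 17.8 points for U at position 1 and 8.39 for U at position 29, and the 6 h minus 3 h difference was 16.3, -8.10 and 8.51 points for U at position 1, A at position 27 and U at position 29. Over the mean of all positions these were 16.6 and 7.19 points, with -7.33 for A at position 27, and 15.8, -7.35 and 7.94 points. These settings subtract the shift in overall composition by construction. Leaving out zeros put 52.0% of ddG values below 0. Of 246 alternatives for the other 86 results, which include medians over lengths as well as single positions, 72 moved and 236 kept their sign. Of the 10 that lost it, only 1 belonged to a difference above 2 interior SDs. This was U at position 2, oxidation-resistant minus whole RNA, at -0.180 points over the mean of all positions. The 10 include the medians over lengths of A and G at position 2, to which the interior SD does not apply. Not run, because the files give no counts or denominators, were lengths weighted by reads, mismatches as a share of mismatched reads, and the most abundant mismatch class alone. The set without 5′ U was not set against the remaining RNAs, since its first bases show that it is not simply part of the profile of all RNAs. The unknown depth limits every share.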

Other observations

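All tests in this part were chosen after the results were seen. In the 29 nt TWI1 knockout RNAs, U at position 1 was 65.9% and A at position 27, which it would face in a duplex with 2 nt 3′ overhangs, was 63.6%. In wild type whole RNA at 3 h these were 72.3% and 63.4%. In oxidation-resistant wild type RNA they were 92.6% and 54.7%, and in wild type whole RNA at 6 h they were 89.9% and 52.6%. Some other facing pairs of the knockout matched less closely, with C at position 2 at 11.5% against G at position 26 at 16.3%, and G at position 3 at 29.6% against C at position 25 at 24.5%. Others matched more closely, with U at position 2 at 26.9% against A at position 26 at 25.7%, and A at position 3 at 38.7% against U at position 25 at 37.1%. G at position 2 and C at position 26 were nearly equal both in the knockout (21.6% each) and at 6 h (22.1% each), so that pair does not set the libraries apart.

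The first pattern weighed is the likeness of U at position 1 and A at the third position from the 3′ end in the 29 nt knockout RNAs. It was weaker in shorter knockout RNAs, where U exceeded A by 20.7 points at 24 nt and 8.46 points at 26 nt, against 2.37 points at 29 nt. Because the likeness was noticed at those end positions, they were left out, and the mean absolute difference between a base and its complement at the facing position was computed over the remaining pairs for 3′ overhangs of 0 to 4 nt. An overhang of 2 nt gave the lowest value at 8 of 9 knockout lengths, 27 nt being the exception, and at 5 of 9 oxidation-resistant lengths; at 29 nt the knockout value was 0.361 of the median for the other overhangs, which equal A and U content alone would not give. At 24 nt that ratio was 0.886, so the shortest knockout RNAs show it weakly. The positions left out face each other at 2 nt but fall in different pairs at 0 and 1 nt. The overhangs were thus not compared over equal sets of pairs. At 29 nt an overhang of 2 nt also gave the lowest value in oxidation-resistant RNA (ratio 0.836) and in wild type whole RNA at 6 h (ratio 0.829). The libraries thus differed at 29 nt in the depth of this minimum and not in its place. A hypothesis is that both strands of duplexes with 2 nt 3′ overhangs may be in the knockout library. Wild type whole RNA at 3 h lay near the knockout, with a ratio of 0.430 at 29 nt. Strand identity was not tested.

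The second pattern is a stepped composition in the set without 5′ U. Taking the most raised base at each of positions 6 to 21 spelled GAUGGUUUAGUGGUAG, and the levels did not overlap: G was 20.8% to 24.2% where raised and 14.8% to 15.8% elsewhere, A 39.4% to 41.1% and 31.8% to 34.9%, and U 35.2% to 37.5% and 28.2% to 31.6%, as an RNA making up 6.64% of the set (SD 1.11 over positions) would give, against 0.525% by the same procedure in a simulated set with no such RNA. That simulated set had the same composition at every position, so its 0.525% leaves out the variation along real RNAs. The raised bases were also picked from the set itself, which by itself widens the gap between levels and raises the 6.64%. If the set were part of all 29 nt knockout RNAs, their profile would hold 2.24% of the sequence. The estimate there was 0.374% (SD over positions 0.926), and the highest estimate in wild type 29 nt RNAs was 0.418%. These low estimates argue against a sequencing-cycle effect common to the libraries. They cannot tell whether the sequence is in the knockout library as a whole, because the set is not simply part of that profile and may have been filtered differently. The bases matched 8 of 8 conserved positions of a tRNA 5′ end when 1 base of the D-loop was taken as missing, and 13 of 10000 shuffles of the same bases did as well when 0, 1 or 2 missing bases were allowed. A tRNA fragment is therefore a candidate source of the steps, but the match was to conserved positions and not to the organism’s own tRNA sequences, no explanation by genotype was tested, and how the set was filtered stays open.

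The third pattern is the likeness between wild type whole RNA at 6 h and oxidation-resistant RNA at 3 h at position 1. Bases not listed at position 1 were 1.20% of 6 h RNAs, too few for the difference of 17.7 points from 3 h whole RNA. If 6 h RNA were a mixture of the 3 h whole and oxidation-resistant RNAs, its shares would lie between theirs. However, 2 of 20 end shares lay outside by more than 2 SDs of the base’s own share over interior positions. Both were at position 28, where A lay below the range by 5.50 points and G above it by 5.74 points. Shares at one position are bound to a fixed sum, so these are not independent departures. The mean absolute difference over all positions was 2.03 points from oxidation-resistant RNA and 2.17 points from 3 h whole RNA, and over interior positions it was 1.72 and 1.43 points, so 6 h RNA was not nearer to oxidation-resistant RNA throughout. A change with time in which RNAs are made or kept may contribute, but with 1 library per time a difference between library preparations stays open.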
